A study of Homo sapiens with 6 samples.

How the data were processed

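RNA from 6 samples of U87 glioma cells was profiled on 1-colour arrays with biotin labelling, 3 samples with miR-151a overexpressed and 3 with the miR-NC control. Groups and replicate numbers were taken from the sample titles. Total RNA was extracted with Trizol and labelled by an Affymetrix whole-transcript protocol, per the labels' protocols. The probe set identifiers look like those of a 3 prime expression array, which is labelled from the 3 prime end, so the labelling is not settled here, nor is what 3 prime to 5 prime ratios say of RNA quality. The deposited values are linear probe set intensities, never 0 or negative, with 1 column per sample and 49395 rows. The submitters' processing notes name MAS5, with no version or role; the background correction, summarization, scaling and normalization are not given in the sources used here. Quantiles were close in all 6 columns, so the arrays had been brought to a similar scale before deposit, and a shift shared by most transcripts would not be seen in these values. Scanner files and detection calls were not used here, so no probe set is said to be absent.

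The 102 control probe sets were left out of the comparisons. Some of them, and the result of 1 of the gene lists, are not reported here. Probe sets were named from the platform annotation, with symbols updated through Entrez identifiers to the RefSeq annotation of GRCh38.p14, from which no coordinates were used. Of 49293 probe sets, 44988 named 1 gene, 1832 several genes and 2473 none; 44961 of the first matched RefSeq. Each of 18132 genes was represented by its probe set with the highest mean log2 value over all 6 samples. Probe sets that name several genes were used only in counts of probe sets.

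Values were transformed as log2(intensity + 1) and compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment over all probe sets or genes and a threshold of 0.05. Fold changes are on the log2(intensity + 1) scale, which understates changes of dim genes. Intervals are 95% intervals of the fit. With 3 samples against 3, an exact permutation test of a single value cannot go below p = 0.1, so p-values come from the model across genes. Figures were drawn with matplotlib 3.10.9.

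A total of 33 gene lists with 893 entries was fixed before the data were examined, of which 834 entries were measured. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists. Camera was also run with the correlation estimated from the data, and 0 lists then passed (9 had an unadjusted p under 0.05; fry called 18). The smallest adjusted p was 0.060. For the checkpoint kinase and cholesterol lists the estimated correlation was 0.00064 and -0.0038, below the preset one. Their camera adjusted p still went from 0.00019 to 0.074 and from 0.0015 to 0.076. The loss of these calls therefore does not come from a higher correlation, and the 2 forms of the test differ in more than that setting. Fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. A further 4 lists were chosen after the first results were seen and appear only among the closing observations. The tests on genes were checked on simulated data drawn from the means and spreads of the 18132 genes in this comparison: 23.4%, 73.9% and 96.4% of changes of 0.25, 0.5 and 1 on the log2 scale were recovered, and 4.34% of calls were false. Far fewer genes were shifted in the simulation than the 15.4% that passed in the data. Recovery depends on that share, so these rates hold for the simulated setting. In 10 simulated draws of independent genes, a list shifted by 0.25 was called in 10 and an unshifted list in 0, at an unadjusted camera p under 0.05. Independent genes do not test how correlation between genes affects such calls.

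Genes named in the text were chosen by a rule written before the data were examined. It took the measured members of the reported miR-151 target list; the 10 largest rises and the 10 largest falls past the threshold with groups that did not overlap and a mean above the median gene level in at least 1 group; up to 4 passing members of each list by smallest p, or at most 2 where none passed; and PTK2 and MGMT. The text gives examples from these genes, and says where a gene was named after its values were seen.

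Alternatives were quantile normalization, median centring, a pseudocount of 32, removal of probe sets below the 0.25 quantile of mean level, a variance trend with a robust fit, array weights, the replicate number as a block, a statistic without variance shrinkage, a change of at least 1 on the log2 scale, the mean over a gene's probe sets, and leaving out each sample in turn. For camera, the trend alternative used a variance trend without the robust step. The estimated correlation was also run without each sample in turn, for lists that camera called only then; this was chosen after the data were seen. A planned test of genes with microRNA seed matches in 3 prime untranslated regions was not run, since it needs transcript sequences, which were not used here.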

Results

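Messenger RNA levels were measured on 1-colour Affymetrix arrays in U87 cells, an established human glioblastoma line, that overexpressed either the microRNA miR-151a or a negative control microRNA (miR-NC). Each group held 3 samples. The series addresses which transcripts differ when miR-151a is raised, and miR-151a has been studied in glioma for its link to the DNA repair gene XRCC4 and to temozolomide, an alkylating drug. No drug treatment is named in the labels. The 6 arrays had nearly equal distributions, with median probe set intensities from 57.1 to 58.6. Pearson correlations of log2 intensities over probe sets lay between 0.9980 and 0.9984 within groups and between 0.9956 and 0.9958 between groups, and the first principal component held 56.6% of the variance. Nothing in the labels says that the 3 samples of a group were separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision: the median within-group SD was 0.080 on the log2 scale.

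Cells with miR-151a had higher levels of most genes of the inflammatory, ATF4 and unfolded protein response and p53 target lists and lower levels of most genes of the cell cycle lists, and the large changes were rises. Of 18132 genes, 2788 passed a Benjamini-Hochberg adjusted p of 0.05 in limma, of which 1318 rose and 1470 fell. The median change was 0.33 on the log2 scale among the genes that rose and -0.26 among those that fell. A change of at least 2-fold was found for 78 genes that rose and for 0 genes that fell, and at an unadjusted limma p under 0.05 these counts were also 78 and 0. The 78 rises of this size became 39 with a pseudocount of 32, which lowers the folds of dim genes, and 60 with the mean over probe sets, with 0 falls in each of these limma fits, also at an unadjusted p under 0.05. The values of the groups did not overlap for 34.5% of genes, where chance gives 10%. At the level of probe sets, 6940 of 49293 passed, 3355 higher and 3585 lower. This count dropped to 4503 without miR-151a replicate 3 and to 4082, 4130 and 4290 without miR-NC replicates 1, 2 and 3; the lower ones numbered 2052, 2276, 1893, 1959 and 2001 without miR-151a replicates 1 and 3 and miR-NC replicates 1, 2 and 3, and the higher ones 2227, 2189 and 2171 without miR-151a replicate 3 and miR-NC replicates 1 and 2. The single probe set that fell by 2-fold or more was a dim one for the chaperonin HSPD1, at -1.04, named here after its value was seen, while 5 brighter probe sets of that gene lay between -0.04 and 0.07. Leaving out 1 sample reduced the number of changed genes to between 1706 and 2015, with 1745, 1706 and 1721 without miR-NC replicates 1, 2 and 3. The number of genes that fell dropped to 916 and 936 without miR-151a replicates 1 and 3, and to 826, 817 and 800 without miR-NC replicates 1, 2 and 3.

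**Figure D1:**
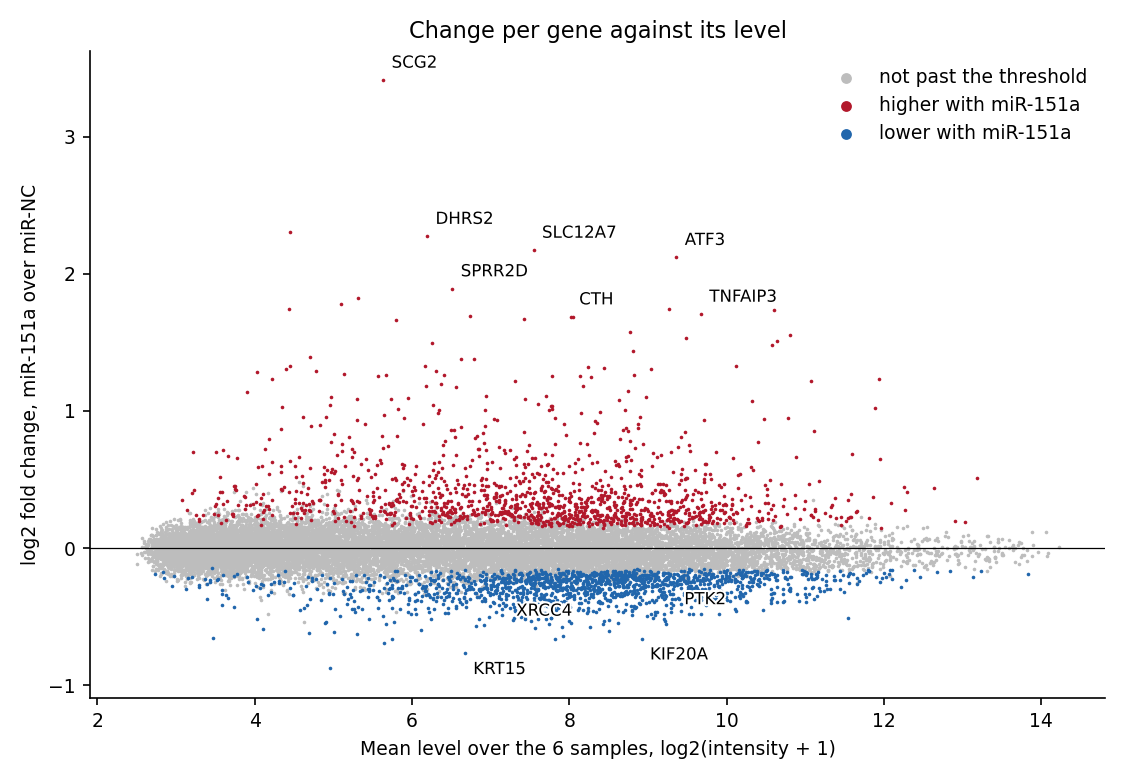
Log2 fold change of miR-151a over miR-NC (vertical axis) against mean log2(intensity + 1) over the 6 samples (horizontal axis), 1 point per gene, for 18132 genes. Red points are the 1318 genes that rose and blue points the 1470 that fell at an adjusted p under 0.05; SCG2 stands highest at 3.41, and the lowest changed gene, GABRB1, at -0.88.

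SCG2, which encodes the secretory granule protein secretogranin II, had the largest rise among the genes above the median level in at least 1 group. Its intensity was 161 ± 6.54 (SD, n = 3) with miR-151a and 14.3 ± 1.47 (SD, n = 3) with miR-NC, a 10.6-fold rise on the log2(intensity + 1) scale (adjusted p = 1.1e-06). The miR-NC level lay near the lower quartile of the arrays, 14.9 to 15.6, and the log2 fold change of 3.41 became 2.06 with a pseudocount of 32, so the size of this rise is uncertain. DHRS2, a short-chain dehydrogenase, rose 4.83-fold, the stress-induced transcription factor ATF3 rose 4.34-fold and the cornified envelope gene SPRR2D rose 3.71-fold. Over the alternatives their log2 fold changes ran from 1.58 to 2.34, from 1.45 to 2.16 and from 1.40 to 1.94, so the sizes of these folds depend on the processing. The stress protein gene NUPR1 rose 3.35-fold, TNFAIP3, an inhibitor of NF-kB signalling, 3.26-fold, the adaptor gene TRAF1 3.23-fold and CTH, an enzyme of cysteine synthesis, 3.22-fold. Probe sets disagreed for the other genes of this group: 1 of 2 probe sets for SLC12A7 rose, by 2.17 on the log2 scale, with the dimmer one at 0.07, and 1 of 4 for RAP1A rose, by 1.74, with the rest between -0.08 and 0.01. Falls were smaller. Over all levels the largest was that of the dim gene GABRB1, at -0.88, named after its value was seen. Among genes above the median level in at least 1 group, KRT15, a keratin, fell by 41.2% from 132 ± 3.40 (SD, n = 3) to 77.4 ± 4.68 (SD, n = 3; adjusted p = 0.00019). KIF20A, a mitotic kinesin, fell by 36.7%, and the kinetochore genes NUF2 and SPC24 fell by 33.0% and 33.0%. TMEM255A fell by 33.3%. For HIRA, PUS7L, TLN1, TNFSF13B and TMT1A the brightest probe set fell, by 0.57 to 0.66 on the log2 scale, and the gene's other probe sets did not pass. With the mean over probe sets the log2 fold change was 1.12 for SLC12A7, 0.41 for RAP1A, -0.32 for SPC24 (-0.58 by its brightest probe set) and between -0.37 and -0.26 for PUS7L, TLN1 and TMT1A.

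XRCC4, the partner of DNA ligase IV in non-homologous end joining, was lower with miR-151a. Its brightest probe set had an intensity of 132 ± 6.93 (SD, n = 3) with miR-151a and 167 ± 11.05 (SD, n = 3) with miR-NC. The log2 fold change was -0.34 with a standard error of 0.06 and a 95% interval from -0.49 to -0.19 (adjusted p = 0.012), and the 3 values with miR-151a all lay below the 3 with miR-NC. Of its 4 probe sets, 2 fell past the threshold over all probe sets, and the other two lay at -0.17 and -0.16. XRCC4 was the 1 measured gene of 5 reported miR-151 targets that passed, and 1 passed when adjusted over the list alone. Of all genes, 15.4% passed. As a list these targets were not called by camera (adjusted p = 0.80, median -0.05, and adjusted p = 0.85 with an estimated correlation). Fry gave an adjusted p of 0.018. Which arm of miR-151a was expressed, how, and for how long is not given in the sources used here, so these counts do not say how many targets of the expressed arm changed. Whether XRCC4 was reported as a target from these same samples is not given either, so its fall is not an independent check of that report. The other measured targets had log2 fold changes of 0.16 for ARHGDIA, 0.06 for ATP2A2, -0.05 for CDH1 and -0.09 for TWIST1, with adjusted p from 0.11 to 0.71. The probe sets of ATP2A2 disagreed: of 6, the brightest and 1 other were at 0.06, 3 lay between -0.23 and -0.16, and 1 was past the threshold as lower, at -0.25. With the mean over probe sets ATP2A2 was at -0.12 (adjusted p = 0.068, range over the alternatives 0.068 to 0.59). For ARHGDIA, 3 of its 4 probe sets were past the threshold and higher, and its brightest one was not past it. The adjusted p of ARHGDIA ranged from 0.0072 to 0.28 over the alternatives and was 0.0079 with the mean over probe sets. PTK2, the host gene of miR-151a, fell by 16.3% (log2 fold change -0.26, adjusted p = 0.016), and its adjusted p was 0.053 without miR-NC replicate 1, within a range from 4.7e-05 to 0.062 over the alternatives. MGMT, which reverses temozolomide-induced methylation of guanine, had an intensity of 8.74 ± 1.26 (SD, n = 3) with miR-151a and 8.67 ± 0.959 (SD, n = 3) with miR-NC, below the lower quartile of every array, and its log2 fold change of 0.01 had a 95% interval from -0.24 to 0.25.

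**Figure D2:**
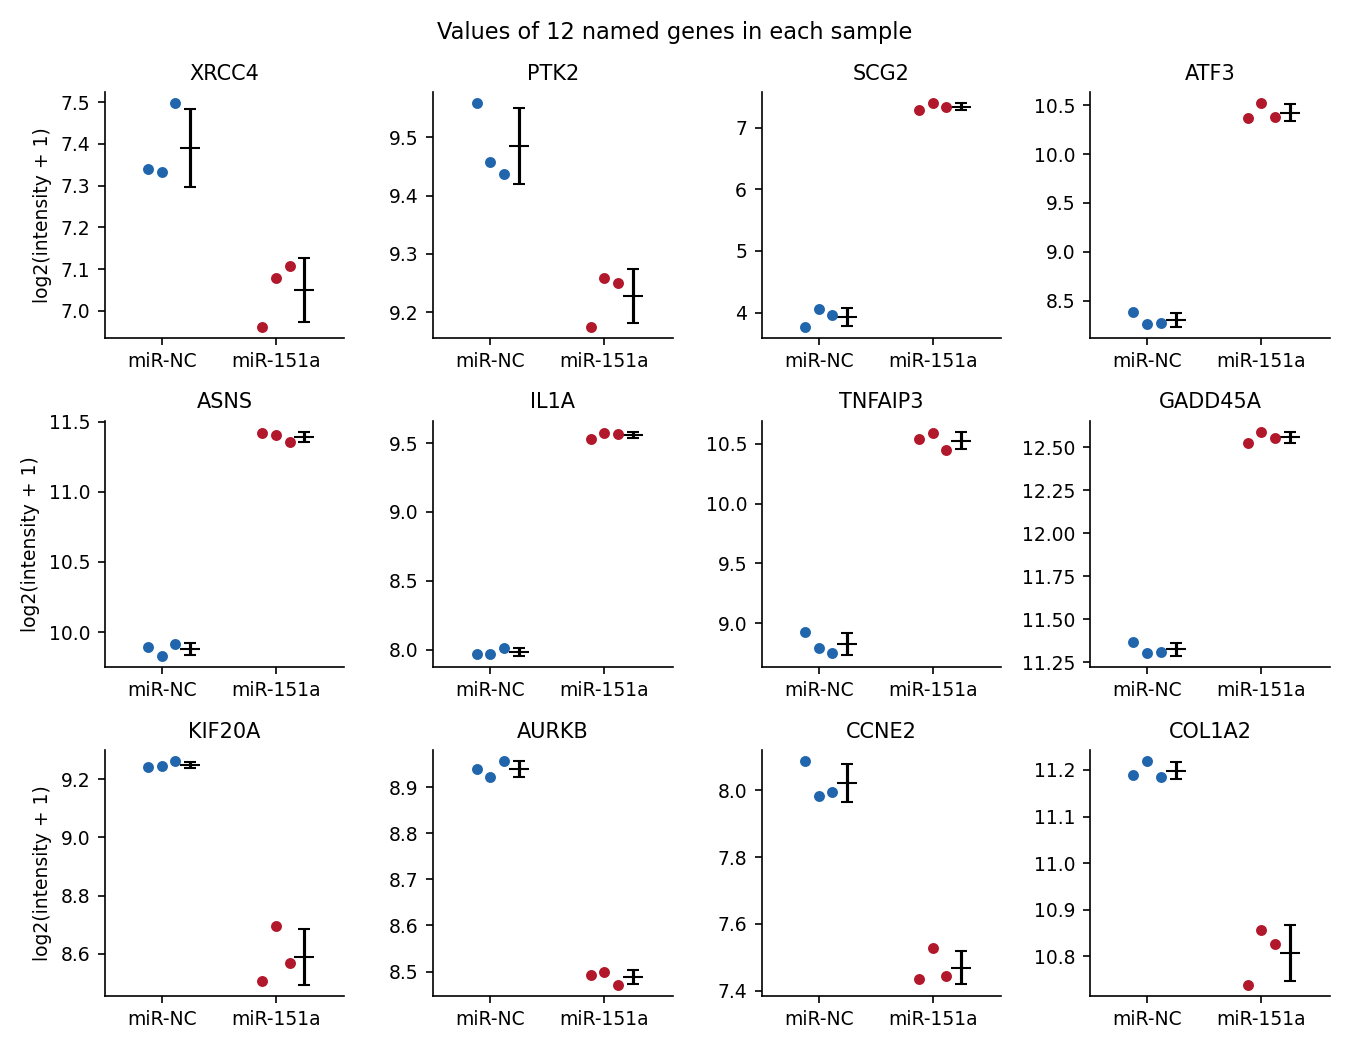
Log2(intensity + 1) of 12 genes in each of the 3 miR-NC (blue) and 3 miR-151a (red) samples, with the mean and SD of each group in black; each panel has its own vertical range. In all 12 panels the groups do not overlap, and the distance between them is 0.34 for XRCC4 and 3.41 for SCG2. Most of these genes were chosen for groups that do not overlap or for a small p, so the lack of overlap is not a separate result.

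Other DNA repair genes moved in both directions. Among 18 measured genes of non-homologous end joining, 2 rose and 3 fell. LIG4, the ligase that binds XRCC4, rose by 22.8% (adjusted p = 0.0055), and TP53BP1, a break-site scaffold gene, had a log2 fold change of 0.33. Adjusted over the list alone, 2 rose and 4 fell. Among 25 genes of homologous recombination and the Fanconi pathway, 3 rose and 7 fell, and adjusted over the list alone 4 rose and 10 fell. The helicase gene BLM rose by 53.3%. Among 26 genes of alkylation damage repair, 1 rose and 5 fell, with the glycosylase gene NEIL3 at -0.31, and adjusted over the list alone 1 rose and 7 fell. None of these 3 lists passed limma's camera test against other genes (adjusted p = 0.44, 0.14 and 0.15), but without miR-151a replicate 3 the homologous recombination list passed, as lower, with an adjusted p of 0.045 in a range from 0.045 to 0.29 without 1 sample; the adjusted p was 0.58 with an estimated correlation in these samples. Without miR-151a replicates 1, 2 and 3 and miR-NC replicates 1, 2 and 3 in turn, its 7 falls became 2, 3, 4, 2, 1 and 1, and the 5 falls of alkylation repair became 2, 2, 2, 3, 1 and 2 with 0 rises in each of these limma fits. The 3 rises of homologous recombination became 1 without miR-NC replicate 1, and the 3 falls of end joining became 1 without miR-NC replicate 1 or 3.

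Inflammatory genes rose together. Of 29 measured genes of the NF-kB and inflammatory cytokine list, 22 rose and 0 fell, with a median log2 fold change of 0.54; adjusted over the list alone, 25 rose. The cytokine gene IL1A rose 2.98-fold from 252 ± 4.58 (SD, n = 3) to 752 ± 11.7 (SD, n = 3), and the chemokine genes CXCL3 and CCL20 had log2 fold changes of 1.33 and 1.31. The camera adjusted p was 2.9e-24 with the preset correlation, and the adjusted p was 0.060 with an estimated correlation. The log2 ratio of the 3 prime to the 5 prime control probe set, a sign of RNA quality where labelling starts at the 3 prime end, which is not settled here, differed between miR-151a and miR-NC samples by -0.11 for beta-actin (95% interval -0.17 to -0.06) and by 0.0063 for GAPDH (-0.012 to 0.025), beside this and all other lists. For 18S ribosomal RNA the log2 ratio of the 3 prime probe set to the 5 prime and middle ones was higher with miR-151a by 0.80 (0.71 to 0.88). Interferon-stimulated genes did not pass as a list (adjusted p = 0.17), with 3 of 34 higher, among them IFI35 at 0.42, and 1 lower, IFI6 at -0.27; the 3 rises became 1 without miR-151a replicate 2 or any of miR-NC replicates 1, 2 and 3. Immune cell markers had a median of 0.01, with 1 of 19 higher and 1 lower: the macrophage receptor gene CD163 had a log2 fold change of 0.66 and the class II gene HLA-DRA had -0.38. With a pseudocount of 32 CD163 was at 0.20, and with the mean over probe sets HLA-DRA was at -0.25. Without miR-151a replicate 2 the count of higher markers became 2.

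Genes of the ATF4 and unfolded protein response list rose in part. Of 35 genes, 22 rose and 4 fell, with a median of 0.43, and adjusted over the list alone 22 rose and 6 fell. Among the genes that rose were the amino acid genes ASNS (asparagine synthesis), which rose 2.85-fold from 941 ± 26.6 (SD, n = 3) to 2686 ± 63.4 (SD, n = 3), CTH, and SLC3A2, an amino acid transporter subunit, at 1.48. The genes that fell were the endoplasmic reticulum chaperone or folding genes HSP90B1 at -0.21, HYOU1 at -0.22, CALR at -0.24 and PDIA4 at -0.22, named after their values were seen. The camera adjusted p was 2.3e-11, and the adjusted p was 0.076 with an estimated correlation. With the mean over probe sets CALR did not pass (adjusted p = 0.055, range over the alternatives 0.00038 to 0.069). Of the probe sets of these genes, 1 of 7 for HSP90B1, 3 of 9 for HYOU1, 1 of 2 for CALR and 2 of 3 for PDIA4 fell past the threshold. With the replicate number as a block in limma, HSP90B1, CALR and PDIA4 did not pass (adjusted p = 0.055, 0.069 and 0.096), while HYOU1 did (0.0496). The count of 4 falls became 2 without miR-151a replicate 1 or 3 or miR-NC replicate 1, 1 without miR-NC replicate 2 and 0 without miR-NC replicate 3.

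Of 24 p53 target genes, 17 rose and 0 fell, with a median of 0.30, and adjusted over the list alone 18 rose. GADD45A, a growth arrest gene, rose 2.35-fold from 2566 ± 67.0 (SD, n = 3) to 6032 ± 127 (SD, n = 3). GDF15, a stress-induced secreted factor, had a log2 fold change of 1.07, SESN2 0.85 and the kinase gene PLK3 0.72. The camera adjusted p was 1.1e-12, and the adjusted p was 0.074 with an estimated correlation. Of 26 immediate early genes, 8 rose and 2 fell, also when adjusted over the list alone. The transcription factor genes EGR1 and KLF10 were both at 0.95, and those that fell were FOSL1 at -0.31 and KLF2 at -0.23, of which KLF2 was named after its value was seen. Averaged over probe sets, EGR1 was at 0.55, FOSL1 at -0.17 and KLF2 at -0.15. This list had a camera adjusted p of 0.0019, and the adjusted p was 0.14 with an estimated correlation. The count of 8 rises became 5 without miR-151a replicate 3, miR-NC replicate 2 or miR-NC replicate 3, and the count of 2 falls became 1 without miR-NC replicate 2, where KLF2 had an adjusted p of 0.056 (range over the alternatives 0.00012 to 0.056).

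Genes of cell division fell. All 32 measured genes of G2/M and mitosis fell, with a median of -0.39, also when adjusted over the list alone. AURKB, a mitotic kinase, fell by 26.8% from 489.8 ± 5.85 (SD, n = 3) to 358 ± 3.60 (SD, n = 3), and ASPM, a spindle gene, had a log2 fold change of -0.46. Of 33 genes of G1/S and DNA replication, 23 fell and 0 rose, with a median of -0.27, and adjusted over the list alone 29 fell. CCNE2, a G1/S cyclin, was at -0.55, and RFC3 and POLE2, a clamp loader and a DNA polymerase subunit, were both at -0.39. The camera adjusted p was 1.7e-24 for G2/M and 7.4e-16 for G1/S, and for each the adjusted p was 0.060 with an estimated correlation. Of 18 genes of DNA damage checkpoint kinases and their partners, 8 fell and 0 rose, and adjusted over the list alone 10 fell. WEE1, which holds back mitotic entry, was at -0.38, and CDC25A and CDC25B, phosphatases that promote it, were both at -0.39; with the mean over probe sets CDC25B was at -0.22. The camera adjusted p of this list was 0.00019, and the adjusted p was 0.074 with an estimated correlation. Its count of 8 became 4 without miR-151a replicate 1 or miR-NC replicate 2 and 5 without miR-151a replicate 3 or miR-NC replicate 1.

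**Figure D3:**
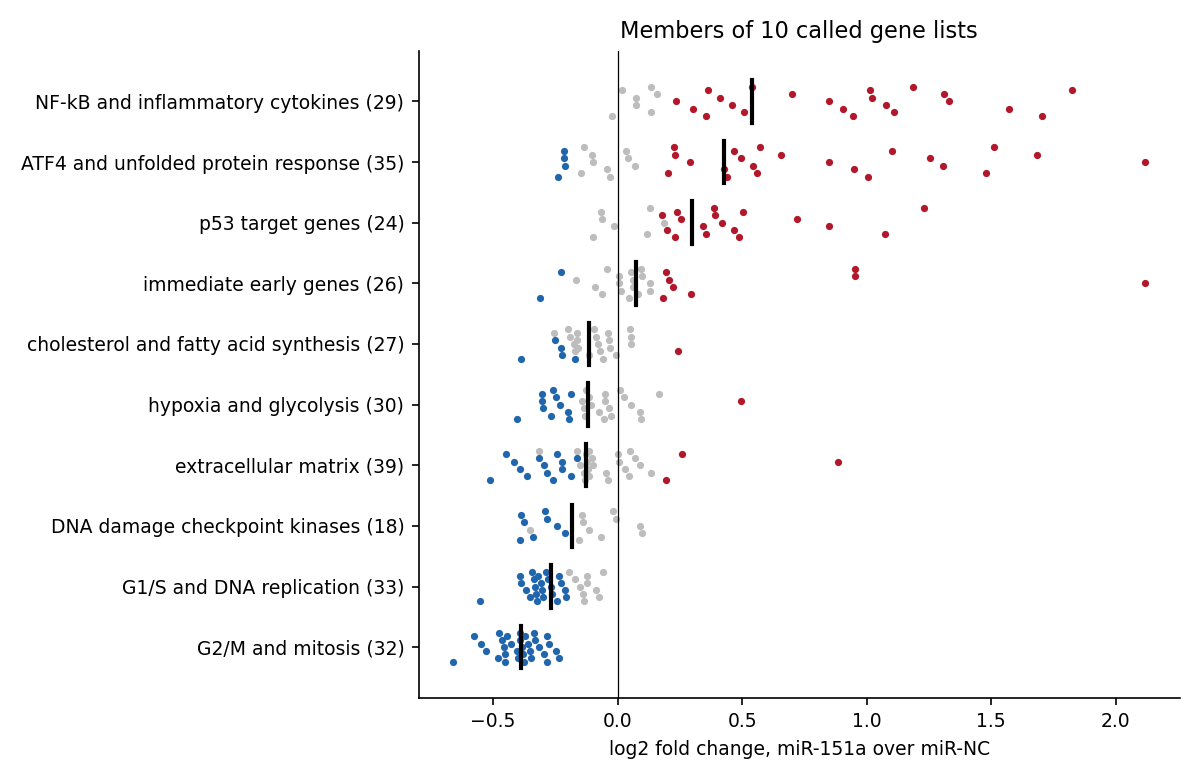
Log2 fold change of miR-151a over miR-NC for each measured member of 10 of the 11 lists called by camera with the preset correlation, 1 point per gene, with the number of members in parentheses and the list median as a black bar. Red points rose and blue points fell at an adjusted p under 0.05 and grey points did not pass; the medians run from -0.39 for G2/M and mitosis to 0.54 for NF-kB and inflammatory cytokines.

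Smaller shifts were found in 3 further lists, each lower. Of 39 extracellular matrix genes, 14 fell and 3 rose (adjusted over the list alone 19 and 3), with TIMP2, an inhibitor of metalloproteinases, at -0.51, the crosslinking enzyme gene LOXL2 at -0.42 and the collagen gene COL1A2 at -0.39. The genes that rose were the proteoglycan genes LUM at 0.88 and DCN at 0.26 and the matricellular gene CCN1 at 0.19, of which DCN and CCN1 were named after their values were seen. Averaged over probe sets, TIMP2 was at -0.30 and LOXL2 at -0.25, and with a pseudocount of 32 DCN was at 0.11. The 14 falls became 9 without miR-151a replicate 1 or miR-NC replicate 1, and the 3 rises became 1 without miR-151a replicate 3 or any of miR-NC replicates 1, 2 and 3. Of 30 hypoxia and glycolysis genes, 11 fell and 1 rose (adjusted over the list alone 14 and 2); NDRG1 was at -0.30, with 1 of its 6 probe sets past the threshold, and the gene that rose was DDIT4, a stress-induced inhibitor of mTOR, at 0.50. With the mean over probe sets NDRG1 did not pass (adjusted p = 0.069, range over the alternatives 1.3e-06 to 0.069), nor did DCN (0.18, range 0.014 to 0.18) and CCN1 (0.058, range 0.0027 to 0.081). The 11 falls became 7 without miR-151a replicate 2 or 3, 6 without miR-NC replicate 1 and 5 without miR-NC replicate 2, and without miR-151a replicate 1 the count of rises became 2. With the mean over probe sets 8 of these 30 genes fell and 3 rose, and the camera adjusted p was 0.041. Of 27 cholesterol and fatty acid synthesis genes, 5 fell and 1 rose (adjusted over the list alone 13 and 1), with the desaturase gene SCD at -0.39 and the sterol cyclase gene LSS at 0.24. The 5 falls became 2 without miR-151a replicate 3 or miR-NC replicate 3, 3 without miR-NC replicate 1 and 1 without miR-NC replicate 2. They became 13 with a pseudocount of 32, 14 with a variance trend and robust fit and 4 with the replicate number as a block. The camera adjusted p was 0.00032, 0.0016 and 0.0015 for these 3 lists in turn, and the adjusted p was 0.15, 0.42 and 0.076 with an estimated correlation.

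The remaining lists were not called by camera. Markers of other cell types gave camera adjusted p of 0.23 for astrocytes, 0.99 for neurons, 0.61 for oligodendrocytes, 0.39 for endothelium and 0.15 for epithelium; the keratin gene KRT7, at 1.33 on the log2 scale, was the 1 of 15 epithelial markers that rose. Without miR-151a replicate 3 the epithelial list passed, as higher, with an adjusted p of 0.036 (range without 1 sample 0.036 to 0.38; adjusted p = 0.39 with an estimated correlation in these samples), and 2 of its genes rose, as also without miR-151a replicate 2. The astrocyte transcription factor gene SOX9 was at -0.31 and the oligodendrocyte gene UGT8 at -0.37. Replication-dependent histone genes had an adjusted p of 0.50, with H2AC6 at 1.22 and H2BC9 at -0.54. Autophagy and lysosome genes had an adjusted p of 0.081, with MAP1LC3B at 0.85 and LAMP2 at -0.39. Apoptosis regulators had an adjusted p of 0.44, with BCL2A1 at 0.83 and BIRC5 at -0.28. Epithelial-mesenchymal transition regulators had an adjusted p of 0.96, with CLDN1 at 1.78 and SNAI2 at 0.29. With a pseudocount of 32 CLDN1 was at 0.93, BCL2A1 at 0.42 and H2BC9 at -0.27, and with the mean over probe sets CLDN1 was at 1.12 and BCL2A1 at 0.44. Adjusted p was 0.43 for mesenchymal and 0.66 for stem and proneural glioma markers, 0.90 for drug efflux transporters, 0.79 for microRNA machinery, 0.39 for oxidative phosphorylation, and 0.38 for both ribosomal proteins and heat shock proteins. For 7 of the 33 lists the median, the mean and the test differed in sign; none of the 7 was called.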

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

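The tests of background, immune cells, genes of like level, RNA quality, batch and control probe sets were chosen only after the result was seen; those of the splits and of rescaling were set before. Groups of 3 samples were too small for a test of outlying samples. Control probe sets, which were left out of the comparisons of genes and lists, were compared between the groups in 18 families, and those past an adjusted p of 0.05 in limma are given here. The 3 prime probe set for 18S ribosomal RNA was higher by 0.77 on the log2 scale and the middle one by 0.054. The poly-A spike-in controls, bacterial transcripts added to RNA before labelling, were higher by 0.20 for dap, 0.20 for thr and 0.14 for lys. These 5 were higher in 3 of 3 miR-151a samples. A further 3 families were lower: the 5 prime probe sets for 18S at -0.11 and for 28S ribosomal RNA at -0.18, and the 3 prime one for beta-actin at -0.084. The exact permutation p of each was 0.1, the smallest 3 samples against 3 can give.

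For these controls, brighter labelling of the miR-151a arrays as a whole would raise the 18S probe sets alike. The 3 prime probe set rose by 0.80 (95% interval 0.71 to 0.88) more than the mean of the 5 prime and middle ones, which argues against it as the whole cause. The poly-A controls rose by 0.11 (95% interval 0.05 to 0.17) more than the hybridization controls, which are added after labelling. This is consistent with slightly more spike-in relative to sample RNA at labelling in the miR-151a samples. No biological explanation was tested for either.

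The large changes were rises: 78 genes rose and 0 fell by 2-fold or more in limma, at adjusted and at unadjusted p under 0.05 alike (39 and 0 with a pseudocount of 32). Scaling before deposit stays open: 100% of such genes also rose under quantile normalization and under median centring, but the arrays were already on a similar scale and the largest move of an array was 0.027 (median over probe sets), so this decides nothing. Falls hidden near the background would leave rises and falls balanced among bright genes, but among 6899 genes with a control mean at least 1 above the median log2 level, 26 rose and 0 fell by 2-fold (two-sided exact binomial p = 3.0e-08, with genes taken as independent). At a change of at least 0.5, 116 of these genes rose and 27 fell. A response to miR-151a that acts mainly through induced genes also stays open, as a hypothesis.

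Stress, inflammatory and p53 lists rose while cell cycle lists fell. Immune cells in the miR-151a cultures that raised most immune markers as much as the inflammatory list would give a median near 0.54. The upper 95% bootstrap bound of the median over 19 immune markers was 0.043, which argues against a rise of that size in the markers as a set. Cells of 1 type, which would raise only some markers, are not excluded by a median: CD163 was at 0.66 and HLA-DRA at -0.38. Quantile normalization and median centring left at least 0.948 of each median of the 5 lists with the smallest camera p, which decides nothing on such arrays. Scaling by level would move genes of like level alike. The 95% bootstrap interval of the difference from other genes in 20 level classes lay 0.32 from 0 for G2/M, 0.36 for inflammatory, 0.18 for G1/S, 0.22 for p53 and 0.083 for ATF4 genes. The 5 lists were picked by their p in these same data, so these distances may be too large. For G2/M, inflammatory, G1/S and p53 genes the values argue against scaling by level as the whole cause. ATF4 genes missed the 0.1 set for this test, run on the 5 lists together and then 1 by 1. In a count added later, 22 of 35 ATF4 genes had a 95% interval more than 0.1 above their class, against 8.62% of other genes. The one-sided exact binomial p was 1.9e-15, with genes taken as independent. Against scaling by level, the ATF4 list thus has only a count chosen after that miss. RNA quality stays open too, also because the labelling that these ratios depend on is not settled: the log2 ratio of the 18S 3 prime probe set to the 5 prime and middle ones was higher by 0.80 (95% interval 0.71 to 0.88), the log2 3 prime to 5 prime ratio of the beta-actin controls differed by -0.11 (95% interval -0.17 to -0.06) and that of GAPDH by 0.0063 (-0.012 to 0.025). A culture or handling batch and miR-151a itself cannot be told apart, since 0 samples carry a batch label.

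Among the 10 splits of the 6 samples into 3 and 3, the real one gave 6940 changed probe sets and 2788 changed genes, and the highest of the other splits gave 0 and 0; 1 split, the real one, reached each count. At an unadjusted p under 0.05 limma gave 5223 genes for the real split and between 347 and 813 for the others. For gene lists the real split gave 11 and the highest other 8, and 1 split reached 11. With 10 splits the share cannot go below 0.1, which is too few to exclude chance. The other splits called 4 to 8 lists by camera with the preset correlation although they called 0 genes, and their smallest adjusted p was 1.7e-06 against 1.7e-24 for the real split. With an estimated correlation each split called 0 lists. Each other split mixes the groups unevenly, so it keeps part of the real difference and adds the rest to the spread within groups. Neither its list calls nor its count of 0 genes is then a no-change level. The calls of checkpoint kinase, extracellular matrix, cholesterol, hypoxia and immediate early genes, at 0.00019 to 0.0019, are of a size these splits also reached. The splits therefore do not decide on these calls.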

How the results depend on the processing

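Seed-site tests were planned and not run, as no transcript sequences were used here. All alternatives here were set before the data were examined, and the cause of a change was not tested unless stated. The 11 called lists kept their direction and their call under the alternatives run on lists, except the estimated correlation, where 0 passed. For hypoxia and glycolysis genes the camera adjusted p was 0.041 with the mean over probe sets, near the threshold. Fry called 18 lists. Lists and named genes were not run without variance shrinkage or with a change of at least 1. Between 1636 and 2731 of the 2788 changed genes were also called, in the same direction, under the alternatives that refit the genes at the same threshold, and 1374 were called in all 6 fits without 1 sample.

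Changed probe sets and genes numbered 10649 and 4231 with a variance trend and robust fit (5856 and 2388 lower), and with a pseudocount of 32 there were 5396 and 2218 lower. Without variance shrinkage 4402 probe sets passed (2167 higher, 2235 lower). Requiring a change of at least 1 by construction left 159 probe sets (158 higher, 1 lower) and 78 genes (78 higher, 0 lower; 0 also lower at an unadjusted limma p under 0.05). With the replicate number as a block, which uses up degrees of freedom, 4378 probe sets (2052 lower) and 1727 genes (822 lower) passed and 11 lists were called, and 22 of 127 named genes called in the fit without it lost their call. The numbers do not pair the samples: residuals of same-numbered samples correlated at -0.08, -0.12 and 0.07. Leaving out 1 sample, which lowers the number of samples, gave 4082 to 4805 probe sets (2171 to 2689 higher, 1893 to 2426 lower) and 1706 to 2015 genes (889 to 1097 higher, 800 to 1026 lower).

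Some results turned direction. With the mean over probe sets, SMAD3 went from -0.25 to 0.00284 and GJA1 from -0.23 to 0.023, because their probe sets point both ways. Both had passed and then lost their call (adjusted p = 0.98 and 0.78, with ranges over the alternatives from 7.3e-05 to 0.98 and from 6.4e-06 to 0.78). ATP2A2, which had not passed, went to -0.12. MGMT was at -0.0055 under median centring and between -0.087 and 0.10 without 1 sample; CDH1 was between -0.12 and 0.012 without 1 sample. Among lists that were not called, camera's direction turned for neuron markers (medians -0.020 with quantile normalization, -0.013 with the variance trend and the block, -0.030 with array weights, and -0.071 to 0.032 without 1 sample). It turned for epithelial-mesenchymal transition regulators (medians -0.026 with the trend and array weights, -0.0020 with the mean over probe sets, -0.045 to -0.014 without 1 sample), for immune markers (-0.0059 with the mean over probe sets) and for drug efflux transporters (-0.031 to 0.014 without 1 sample). Fry, a different test, gave these neuron and transition lists (medians -0.013 and -0.026) the direction opposite to camera's. Autophagy and lysosome genes, not called as reported, were called with quantile normalization, a pseudocount of 32, the variance trend, the mean over probe sets and fry. Camera with an estimated correlation did not call them (adjusted p = 0.22). Homologous recombination and ribosomal protein genes were called with the mean over probe sets. XRCC4 passed in the 14 alternatives run on named genes, with log2 fold changes from -0.37 to -0.25 and adjusted p from 0.00023 to 0.037. Without probe sets below the 0.25 quantile of mean level 3362 genes passed among 14389. Dim genes may be limited by the floor of the arrays, but whether this accounts for that count was not tested.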

Other observations

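All 4 lists of this part were chosen after the first results were seen, and so were their tests; HMOX1, OSGIN1 and IRF1 are named after their values were seen. Aminoacyl-tRNA synthetase genes, whose products charge transfer RNAs, rose for 11 of 19 members and fell for 0, with AARS1 at 0.81, WARS1 at 0.77 and GARS1 at 0.69 on the log2 scale. The stress enzyme gene HMOX1 rose 2.93-fold and OSGIN1 rose 2.37-fold. Among 22 other targets of NRF2, the regulator of antioxidant genes, 7 rose and 0 fell, with SRXN1 at 0.71 and TXNRD1 at 0.35. IRF1, an interferon-related transcription factor gene, rose 2.27-fold, and 4 of 16 genes of antigen presentation by MHC class I rose and 0 fell: HLA-B at 0.39, HLA-F at 0.41, HLA-E at 0.26 and HLA-C at 0.16. These 4 are related genes, each read from a probe set of the _x_at type, which can pick up similar sequences, so they may share signal. The other 12 members did not pass and lay between -0.12 for ERAP2 and 0.20 for PSMB8, with TAP1 at 0.053 and B2M at 0.067. Of 23 endoplasmic reticulum folding genes 4 fell and 0 rose, MANF at -0.23, SPCS3 at -0.22, SSR1 at -0.21 and SYVN1 at -0.17. For SSR1 and SYVN1 the limma adjusted p lay near the threshold, at 0.041 and 0.049. Alternatives that refit the genes, also those without 1 sample, were not run on the 4 lists of this part. Adjusted over the list alone, 11 rose and 2 fell among aminoacyl-tRNA synthetases, 8 rose and 1 fell among NRF2 targets, 6 rose and 0 fell among MHC class I genes, and 0 rose and 4 fell among folding genes.

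These lists tested hypotheses on how far the rises extend. That the amino acid response extends to aminoacyl-tRNA synthetases was met by camera, with a median of 0.22 (adjusted p = 1.7e-07). NRF2 targets had a median of 0.092 (adjusted p = 0.0026) and MHC class I genes a median of 0.10 (adjusted p = 0.0016). For each of these the adjusted p was 0.17 with an estimated correlation. Among the other 9 splits of the samples, which called 0 genes in limma (347 to 813 at an unadjusted p under 0.05), camera called these lists in 4, 2 and 3, with lowest adjusted p of 0.0046, 0.0065 and 0.0041. On the lists fixed before, such splits reached 1.7e-06. The other splits keep part of the real difference, so they give no no-change level for these lists. The shifts of NRF2 and MHC class I genes remain weak evidence, with small medians in lists chosen after the first results were seen. That the amino acid response extends to endoplasmic reticulum folding genes was not met. Their median was -0.036, with a direction of lower and a camera adjusted p of 0.051 (adjusted p = 0.28 with an estimated correlation). Among the other 9 splits, camera called this list in 1, with an adjusted p of 0.021. A candidate explanation is a response that raises amino acid genes without the folding branch of the unfolded protein response, which remains a hypothesis found and tested on the same data.

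Of 6995 genes with 3 or more probe sets, 40 had a largest probe set change of 2-fold or more past the threshold. RAP1A was the 1 gene of these 40 where all other probe sets lay within 0.1 of 0. Its changed probe set was the brightest of the 4 and rose by 1.74.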
